A study of Mus musculus with 416 samples.

How the data were processed

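Replication timing was measured in single blastomeres of mouse embryos of the genotype (C57BL/6J x CBA) x DBA/2J. Per the labels' protocols, zygotes were injected with 20 µM of a control siRNA (siCont) or of an siRNA against Rif1 (siRif1) between 17 and 18 hours after hCG. They were then cultured to the 4-cell, 8-cell or morula stage. Embryos were sampled over S phase and taken apart into single cells. The DNA of each cell was amplified over the whole genome with its own barcode before pooled libraries were made, per the labels' protocols.

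The deposited tables, 1 per group, held a value of 0, 1 or NA for each 50-kb bin and cell. The submitters' processing notes list Bowtie2 2.5.1, SAMtools, Picard, bedtools, R 4.2.3 and the genome build GRCm38, without their roles. How reads were turned into states, and which cells were kept, is not given in the sources used here. Read depth per cell is likewise unknown here. Only chromosomes 1 to 19 were in the tables used, so the X chromosome was not analysed here. In all 6 groups the shortest run of 1 state that touched no chromosome end was 5 measured bins (250 kb). The states had therefore been smoothed or segmented before deposit, and finer structure cannot be read from them.

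Of 416 labelled cells, 299 had a column in the tables, and these were used without a further filter. Which value stands for replicated DNA is not stated in the tables. A value of 1 was read as replicated because bins holding the midpoint of a protein-coding gene had a higher mean share of 1 than other bins in all 6 groups, gene-rich DNA being known to replicate early. No pair of cells in a group was identical, and the least different pair of any group differed at 6.37% of its shared bins.

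For each bin and group the percent of measured cells in the replicated state was computed and is called the replicated share. Of 49264 bins, 46015 had at least 10 measured cells in every group and were used. Because groups differed in how far their cells had gone through S phase, each share was centred on the mean over the used bins of its group. The shift of a bin is the centred share in siRif1 cells minus that in siCont cells, in percentage points. A negative shift means that the bin was replicated in relatively fewer siRif1 cells, called later here, and a positive shift is called earlier. Early and late classes were the outer of 5 equal classes of bins ranked by the mean centred share of the control cells at the other 2 stages.

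The labels name no embryo, litter or batch for a cell, so the cells of a group are not independent replicates and each group counts as 1 sample. No p-values or standard errors are given for that reason, and differences are described by their size. Intervals on shares of cells are exact 95% Clopper-Pearson intervals and cover counting error only. A bin was counted as differing by a large amount at 30 points or more. The share of such bins is given beside the share that binomial counting error would give with no difference. How far true sampling error departs from this expectation was not tested.

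Cells were compared in pairs within 5 points of each other in percent replicated, both between 20 and 80%, by Pearson correlation of their states. State switches were counted between neighbouring measured bins in cells between 20 and 80% replicated. Correlations across bins describe profiles, and bins are not independent replicates.

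Genes were placed with a RefSeq table of assembly GRCm38.p6, the build of the files. That table gives no strand, so the bin of a gene's midpoint stood in for that of its transcription start. This choice, the mean over the gene body as its alternative, the gene density values and the rotations of lists described here were chosen after seeing the data. Of 20665 autosomal protein-coding genes, 19410 had their midpoint in a used bin. The 13 gene lists, the comparisons and the rule for named genes were set before the data were examined.

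The rule named, for each stage, the 4 windows of 1 Mb with the highest and the 4 with the lowest mean shift, with up to 3 of their longest protein-coding genes. It also took the 2 members of each list with the largest absolute shift, naming 1 bin once, and Rif1 itself; members of lists with few measured members were left out of the text. A few other items picked by this rule are not reported here. Genes so named are extremes of their lists. Some lie in a named window or in neighbouring bins, so they are not separate findings. The median shift of a list was placed among 10000 random lists of the same size matched in 20 strata of mean centred share. Members of gene clusters share bins, so a second percentile came from 10000 rotations of the list along the genome, after the mean shift of each of 50 strata of centred share had been removed. Both percentiles describe these cells and are not tests. Lists with under 80% of their members measured were not interpreted. These were the 2-cell and genome activation genes, with 12 of 29, and the vomeronasal receptors, with 185 of 352.

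Alternatives covered the cells used, their weight across S phase, matched thinning of both groups over 100 draws, a running mean over 5 bins, size rules of 20 and 40 points, ranks in place of shares and other pair rules. Balanced cells gave equal weight to each 20-point stratum of percent replicated with at least 3 cells in both groups. At the 8-cell stage 3 cells of each group made up 1 of the 4 strata used, and at the 4-cell stage 3 siRif1 cells did. The computations were tested on simulated data drawn from the control shares of each stage. With 200 of 46015 bins moved by 40 points, 85.5, 86 and 86.5% of them passed 30 points at the 4-cell, 8-cell and morula stages. A simulated loss of early-late contrast of 21.9 points at the 8-cell stage was recovered as 21.8. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.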

Results

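Replication states of single blastomeres were compared between embryos that had received an siRNA against Rif1, a chromatin protein known to regulate replication timing, and embryos that had received a control siRNA. The comparison was made at the 4-cell, 8-cell and morula stages. Tables held 49, 60 and 44 siCont cells and 51, 50 and 45 siRif1 cells at these stages. Each cell had a state at 88.1 to 94.1% of the 49264 bins of the autosomes.

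The cells covered much of S phase in every group. The median cell had replicated 42.8% of its measured bins in siCont and 51.1% in siRif1 at the 4-cell stage, with SDs over cells of 24.2 and 19.2. Medians were 48.3 and 43.2% at the 8-cell stage (SD 18.5 and 14.6) and 47.5 and 46.8% at the morula stage (SD 13.9 and 16.7). No siRif1 cell of the 8-cell stage lay above 66.3%, whereas siCont cells of that stage reached 97.3%.

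**Figure D1:**
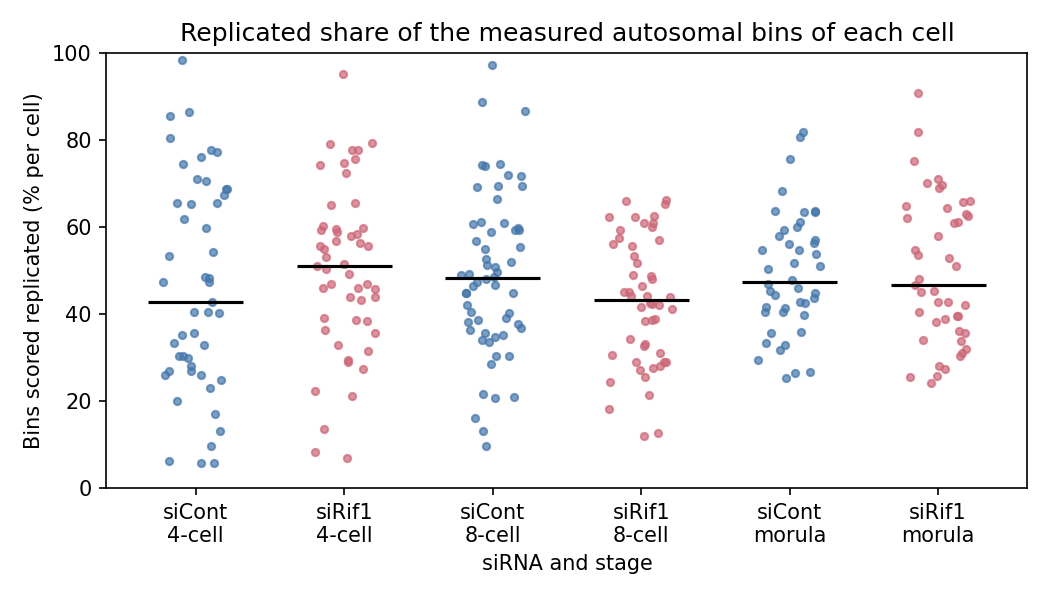
Percent of measured autosomal bins scored replicated in each cell (points), by siRNA and stage, with the group median as a line. Medians lie between 42.8 and 51.1%, and siRif1 cells of the 8-cell stage end at 66.3%.

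At the 8-cell stage early and late regions lay closer together in siRif1 cells than in controls. The earliest of 5 equal classes of bins was replicated in 73.3% of siCont and 56.9% of siRif1 cells, and the latest in 22.4 and 26.9%. After centring, the earliest bins had a shift of -10.2 points and the latest a shift of 10.6 points. The difference between late and early shifts was 20.8 points (SD over autosomes 4.29) and was positive on 19 of 19 autosomes. On percentile ranks this difference was 15 points, so the order of bins differed between treatments as well. With classes drawn from both groups of the same stage it was 14.2 points. How much of the change in order came from counting error was not tested. The SD of the replicated share over bins was 19.8 points in siCont and 14.7 points in siRif1, and it was smaller in siRif1 on 19 autosomes.

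**Figure D2:**
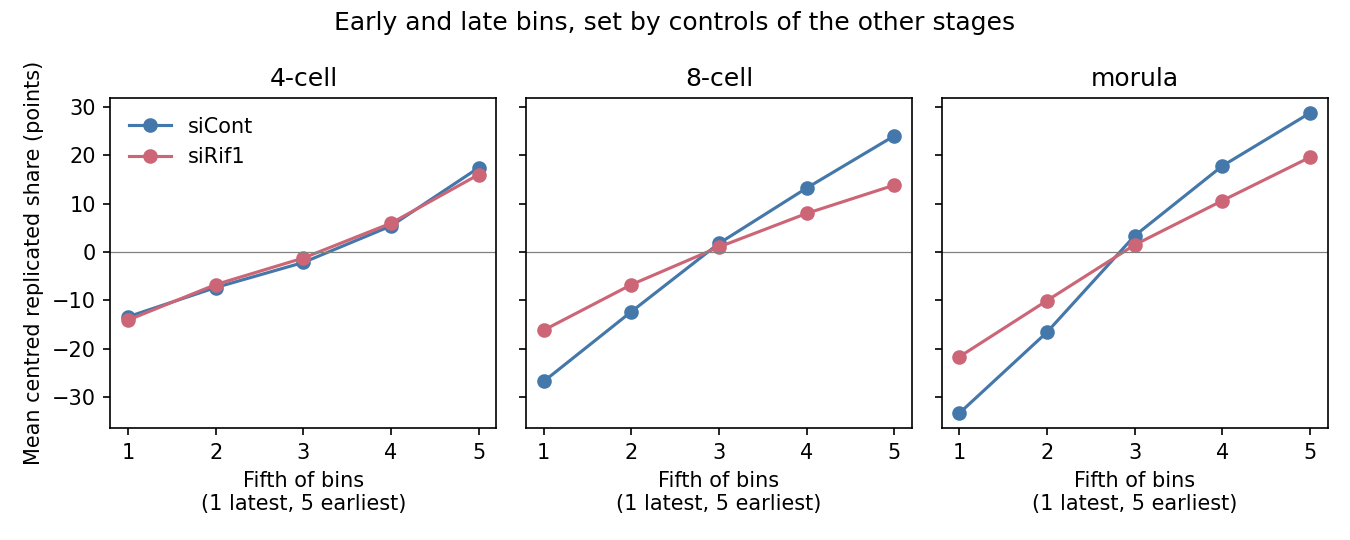
Mean centred replicated share in points (y axis) of 5 classes of bins from latest to earliest (x axis), for siCont (blue) and siRif1 (red) at each stage. The lines overlie at the 4-cell stage, while the siRif1 line is flatter at the 8-cell and morula stages, where late and early shifts differ by 20.8 points.

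The 8-cell windows with the lowest shifts were rich in genes. Chromosome 10 from 81 to 82 Mb, with Gng7, which encodes a G protein subunit, and the transcription factor gene Nfic, was replicated over most of its used bins in 39 of 60 siCont cells (65%, interval 51.6 to 76.9%). In siRif1 this was so in 7 of 49 cells (14.3%, interval 5.94 to 27.2%), a shift of -41.6 points. The adjoining window from 80 to 81 Mb, with Sbno2 and Dot1l, a histone H3 methyltransferase gene, had a shift of -38.3 points. On chromosome 17 the window from 25 to 26 Mb, with Lmf1, Ift140 and Rab11fip3, had a shift of -37.3 points. The window from 27 to 28 Mb, with Anks1, Ilrun and the glutamate receptor gene Grm4, had a shift of -35.6 points. These windows held 51, 54, 50 and 18 protein-coding genes, and only 12 bins of the first were used.

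The 8-cell windows with the highest shifts held few genes. Chromosome 1 from 25 to 26 Mb, with the adhesion receptor gene Adgrb3, was replicated over most of its used bins in 17 of 60 siCont cells (28.3%, interval 17.5 to 41.4%) and 27 of 50 siRif1 cells (54%, interval 39.3 to 68.2%). Its shift was 32 points. Chromosome 1 from 22 to 23 Mb, with Rims1, a gene of the presynaptic active zone, had a shift of 30.3 points. Chromosome 12 from 42 to 43 Mb, with no protein-coding gene, had a shift of 27.4 points, and chromosome 5 from 12 to 13 Mb, with Sema3d, a shift of 25.7 points.

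**Figure D3:**
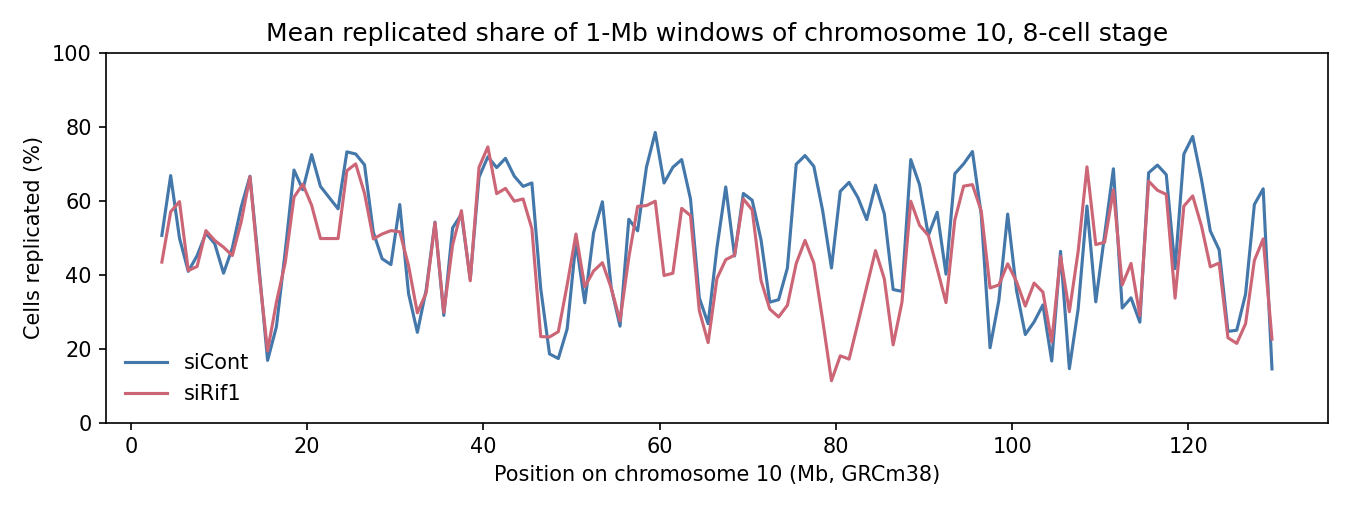
Mean percent of 8-cell stage cells replicated (y axis) in 1-Mb windows along chromosome 10 (x axis, Mb) for siCont (blue) and siRif1 (red). The profiles part most near 80 to 82 Mb, where the siRif1 share is 18.1 and 17.2% and the siCont share 62.6 and 65%.

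Gene lists at the 8-cell stage had medians of both signs. The share of all genes with negative shifts is not given here. The gene-densest of 5 equal classes of bins had a mean shift of -11.0 points, and of -8.16 points at the morula stage. A count of negative members therefore does not by itself set a list apart at either stage. Of 76 ribosomal protein genes, 61 had negative shifts and 15 positive ones, with a median of -11.7 points. Rps10 was replicated in 43 of 60 siCont and 12 of 50 siRif1 cells (shift -41.5 points), and Rps15 in 37 of 60 and 8 of 49 (shift -39.2 points). Both genes lie in windows named above, on chromosomes 17 and 10. Of 37 replication factor genes, 30 had negative shifts (median -8.82 points). They included Cdc6 (-35.4 points) and Cdt1 (-29.5 points), which act in loading the replicative helicase. Of 25 pluripotency genes, 21 had negative shifts (median -10.5 points), among them Pecam1 (-32.6 points) and Pou5f1 (-26.2 points). Trophectoderm genes were negative in 17 of 20 cases (median -9.49 points), with Id2 at -17.2 and the water channel gene Aqp3 at -16.8 points. Zinc finger genes were negative in 241 of 325 cases (median -7.92 points), and Zfp938 (-41.2 points) and Zfp46 (-36.8 points) had the largest shifts.

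Genes of the major histocompatibility complex (MHC) on chromosome 17 had a median of -18.2 points at the 8-cell stage, with 31 of 35 members negative. H2-Q6 and H2-Q10 had shifts of -29.8 and -28.2 points. Long neuronal and fragile-site genes went the other way, with 31 of 39 positive and a median of 8.51 points. Lrp1b, a lipoprotein receptor-related gene, was replicated in 15 of 60 siCont and 25 of 50 siRif1 cells (shift 31.2 points), and Immp2l had a shift of 25.2 points. Olfactory receptor genes had a median of 4.21 points (718 of 1023 positive), although Olfr1375 and Olfr1377 had shifts of -28.8 and -26.7 points. Hox genes had a median of 6.51 points (3.87 with cells balanced over S phase), with Hoxa10 at 9.51 points. Protocadherin cluster genes had a median of 3.85 points (1.74 over gene bodies), with Pcdhb15 at 9.85 and Pcdhb1 at 7.51 points. The histone list had a median of -3.49 points (-1.87 with balanced cells), and its largest shifts were those of H1f0 (-21.8 points) and H13 (-23.8 points), the latter matched by symbol pattern and not a histone gene.

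Against random lists matched on mean share, the ribosomal protein and MHC medians of the 8-cell stage stood at percentiles 7.99 and 0, and under rotation at 0.05 and 4.6. The pluripotency and replication factor medians stood at 38.9 and 59.4 against matched lists and at 0.89 and 4.1 under rotation. Trophectoderm genes stood at 44.8 and 2.42, zinc finger genes at 11.7 and 0.15 and histone genes at 99.6 and 43.5. Among matched lists the pluripotency, replication factor and trophectoderm medians were thus ordinary. Long neuronal genes stood at 99.99 and 93.4, Hox genes at 100 and 96.4, olfactory receptor genes at 99.99 and 19.5 and protocadherin genes at 100 and 69.2. The 2 references thus gave different pictures for several lists. Matched lists were drawn from bins of genes, whereas rotations ran over all used bins, with or without genes. Within the earliest class the gene-densest bins had a shift -14.4 points from that of the gene-poorest. A list in gene-dense bins can therefore stand low under rotation while being ordinary among genes. Hox, protocadherin and histone genes lay in only 13, 11 and 18 bins, so their members are not separate measurements. The 35 MHC genes lay in 28 bins of chromosome 17. The median run of 1 state was 26 bins in siCont and 25 bins in siRif1 at this stage. MHC members are therefore not separate measurements either. With cells balanced over S phase the ribosomal protein median was -19.6 points, in a setting where 3 cells of each group carry 1 of 4 equal weights.

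Profiles of the 2 treatments correlated across bins at r = 0.781 (rho = 0.784) at the 8-cell stage, and least on chromosome 11 (r = 0.662). Chromosome 11 also had the lowest mean shift, -8.32 points, and chromosome 6 the highest, 4.53 points. Bins at least 30 points later made up 1.06% of the genome analysed (486 bins), against 0.0465% from counting error. Bins at least 30 points earlier made up 0.224% (103 bins), against 0.0518%. These shares moved with the cells used, and with cells balanced over S phase the later share was 4.13%. That value leans on the 3 cells of each group below 20% replicated, which carry 1 of 4 equal weights.

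At the morula stage the siRif1 profile was again flatter. The earliest class of bins was replicated in 78.2% of siCont and 69.6% of siRif1 cells, and the latest in 16 and 28.3%. The late and early shifts were 11.7 and -9.16 points, a difference of 20.8 points (SD over autosomes 3.99) that was positive on 19 of 19 autosomes. The SD over bins was 25.8 points in siCont and 17.3 points in siRif1, smaller in siRif1 on 19 autosomes. On percentile ranks the difference was 1.75 points, so the order of the classes was nearly kept while their distance was not. At the 8-cell stage the difference on ranks was 15 points, so the order was less well kept there.

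The morula windows with the highest shifts were late in controls and poor in genes. Chromosome 16 from 67 to 68 Mb, which overlaps the cell adhesion gene Cadm2, was replicated over most of its used bins in 0 of 42 siCont cells (upper limit 8.41%) and 15 of 45 siRif1 cells (33.3%, interval 20.0 to 49%). Chromosome 10 from 16 to 17 Mb, with no protein-coding gene, had a shift of 32 points, from 4 of 44 to 19 of 45 cells. Chromosome 12 from 38 to 39 Mb, with Dgkb and the ETS factor gene Etv1, had a shift of 30.3 points. Chromosome 5 from 82 to 83 Mb had a shift of 28.2 points and held no protein-coding gene.

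The lowest shift of a 1-Mb window at the morula stage was that of chromosome 7 from 43 to 44 Mb, with Zfp936 and Vmn2r126, at -33.2 points over its 15 used bins. It was replicated over most of its used bins in 36 of 44 siCont cells (81.8%, interval 67.3 to 91.8%) and 19 of 43 siRif1 cells (44.2%, interval 29.1 to 60.1%). Chromosome 3 from 79 to 80 Mb, with Rapgef2 and Fnip2, had a shift of -30.6 points. Chromosome 10 from 62 to 63 Mb, with the hexokinase gene Hk1, Tet1 and Stox1, had a shift of -28.8 points. Chromosome 13 from 3 to 4 Mb (10 used bins), with Tasor2, Net1 and Gdi2, had a shift of -28.6 points at the morula stage and 23.8 points at the 4-cell stage.

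Among gene lists, long neuronal and fragile-site genes were positive in 36 of 39 cases at the morula stage (median 14.1 points). Cadm2 had a shift of 30.4 points at its midpoint and Lrp1b a shift of 25.9 points. Protocadherin cluster genes were positive in 57 of 57 cases (median 11.3 points), although with cells balanced over S phase their median was 6.06 points. Pcdhb8 and Pcdha12 had the largest shifts, 18.1 and 16.1 points. Ribosomal protein genes were negative in 69 of 76 cases (median -11.3 points), with Rpl24 at -30.1 and Rps7 at -29.2 points. Replication factor genes were negative in 31 of 37 cases (median -11.2 points), with the helicase gene Mcm5 at -33.1 and Cdc45 at -22.0 points. Pluripotency genes were negative in 22 of 25 cases (median -9.07 points), with Dppa2 and Sall4 both at -24.7 points.

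Trophectoderm genes had a morula median of -4.65 points (-3.09 with balanced cells) with 16 of 20 negative, and Id2 (-33.5 points) and Cdx2 (-20.4 points), a trophectoderm transcription factor gene, had the largest shifts. Zinc finger genes were negative in 257 of 325 cases (median -8.46 points), and Zfp658 and Zfp819 both had shifts of -45.0 points. These genes lie in neighbouring bins of the chromosome 7 window named above. The MHC median was -8.72 points with 20 of 35 negative, and -15.4 points with cells balanced over S phase. H2-Aa and H2-DMb1 both had shifts of -24.4 points. Hox genes had a median of -11.0 points, with Hoxa10 at -21.5 and Hoxd10 at 23 points. The histone list had a median of -11.2 points with 69 of 69 negative, including H1f10 (-22.3 points) and H1f3 (-19.7 points). Olfactory receptor genes had a median of 2.27 points, which was -0.0149 with balanced cells, and Olfr750 and Olfr412 had shifts of -35.5 and -33.3 points.

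**Figure D4:**
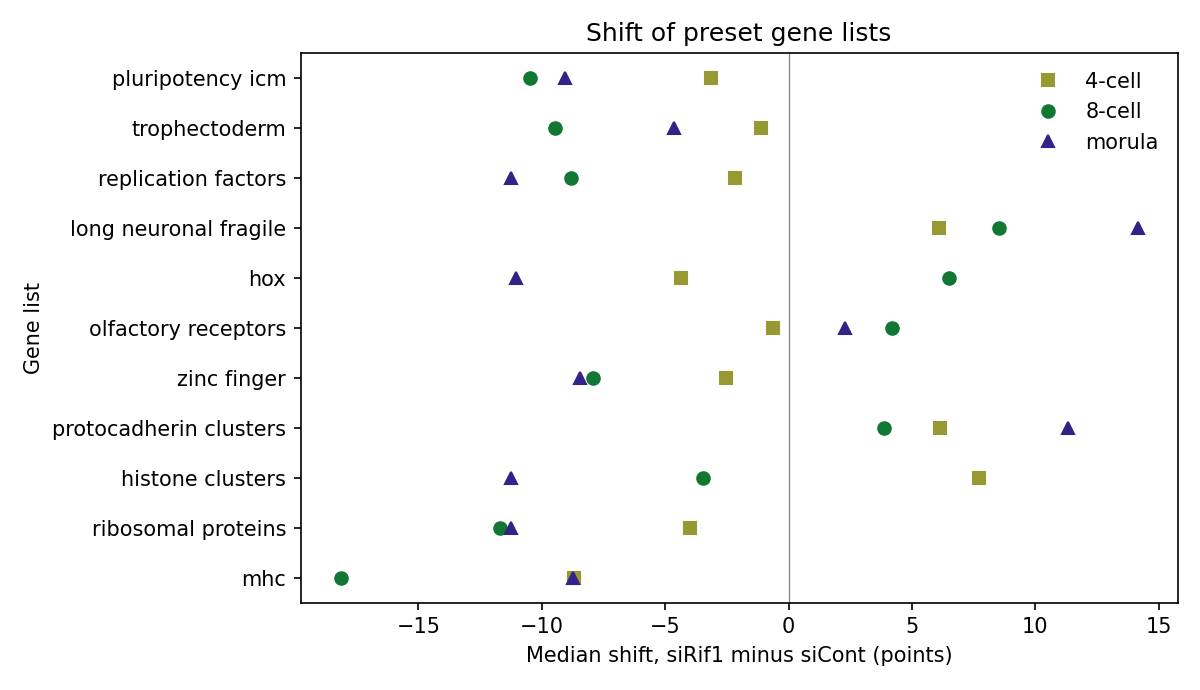
Median shift in points (x axis, siRif1 minus siCont) of 11 preset gene lists (y axis) at the 4-cell (squares), 8-cell (circles) and morula (triangles) stages. Long neuronal and fragile-site genes lie to the right of 0 at each stage, with 14.1 points at the morula stage, and ribosomal protein genes to the left.

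Morula profiles correlated at r = 0.890 (rho = 0.890) between treatments. Bins at least 30 points earlier made up 0.608% (280 bins, 0.106% from counting error), and bins at least 30 points later 0.461% (212 bins, 0.121%). Their order turned with cells between 20 and 80% replicated (0.515 and 0.776%) and with thinned cells (0.864 and 0.974%). The ribosomal protein median stood at percentile 4.34 of matched lists and 0.32 under rotation. The olfactory receptor median stood at 0 in both, below those of other lists of like late timing. Trophectoderm genes stood at 95.7 and 92.8, so their median was less negative than that of most lists of like timing, although their mean shift was -8.40 points. Pluripotency genes stood at 41.7 and 31.9. Replication factor genes stood at 5.65 and 16.6, zinc finger genes at 11.4 and 0.04, histone genes at 0.06 and 15.9, Hox genes at 4.58 and 30.3 and MHC genes at 3.11 and 42. Long neuronal genes stood at 100 and 98.9 and protocadherin genes at 100 and 90.2.

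At the 4-cell stage early and late regions lay about as far apart in siRif1 as in siCont cells. The difference between late and early shifts was 0.728 points (SD over autosomes 3.29), positive on 11 of 19 autosomes. Other choices of cells or ranks gave 2.40 to 2.80 points and classes from the same stage -0.562 points. The SD over bins was 13.7 points in siCont and 14 points in siRif1, and it was smaller in siRif1 on 3 autosomes. This order turned with cells between 20 and 80% replicated (15.1 and 14.5 points) and with thinned cells (14.8 and 14.2 points). Bins at least 30 points earlier or later made up 0.0196 and 0.0435%, below the 0.0988 and 0.0947% from counting error, but 0.231 and 0.123% with cells thinned to matched S phase positions. The profiles correlated at r = 0.789 (rho = 0.778). Counting error had an SD of 6.93 points in siCont and 6.79 points in siRif1 here, and of 5.98 and 6.76 points at the 8-cell stage, where the spread was larger. It therefore lowers the 4-cell correlation more, and the 2 correlations do not rank the stages by likeness.

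The SD of shifts over bins was 8.995 points at the 4-cell stage. Counting error alone had SDs of 6.93 points in siCont and 6.79 points in siRif1. A shift carries the counting error of both groups. Combined as independent errors, these SDs exceed the SD of shifts. The spread of 4-cell shifts over bins thus shows no excess over counting error. The windows and genes named for this stage are extremes picked from many. Whether their shifts exceed counting error was not tested. The 4-cell windows with the lowest shifts held 40, 37, 11 and 29 protein-coding genes. Chromosome 9 from 108 to 109 Mb, with the presynaptic gene Bsn, Dag1 and Slc26a6, had a shift of -27.2 points, from 40 of 49 siCont to 26 of 51 siRif1 cells. Chromosome 8 from 84 to 85 Mb, with the calcium channel gene Cacna1a, Nfix and Mast1, had a shift of -24.3 points. Gse1 and Crispld2 on chromosome 8 from 120 to 121 Mb lay in a window at -23.8 points, and Ppp6r2, Mov10l1 and Syt10 on chromosome 15 from 89 to 90 Mb in one at -23.4 points. The highest window shifts were those of chromosome 5 from 127 to 128 Mb, with Tmem132d (24.4 points), and chromosome 13 from 113 to 114 Mb, with Arl15 (24.1 points).

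Long neuronal and fragile-site genes were positive in 29 of 39 cases at the 4-cell stage (median 6.09 points, 3.91 over gene bodies), with Rbfox1 at 23.9 and Nrg3 at 17.9 points. Histone genes were positive in 65 of 69 cases (median 7.73 points), led by H2ac23 (26.3 points) and H1f5 (22.2 points). Protocadherin genes had a median of 6.13 points, with Pcdhga1 at 11.4 and Pcdhb1 at -9.80 points. MHC genes had a median of -8.69 points but a mean of -2.64 points, with 18 of 35 negative, so that the median lies at the edge of the negative members; H2-Ke6, which lies in that region and encodes no MHC molecule, had -19.0 points and H2-Q10 -15.2 points. Hox genes had a median of -4.36 points (-7.41 with cells between 20 and 80% replicated), with Hoxb13 at -13.3 and Hoxb6 at -11.3 points.

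Ribosomal protein genes had a 4-cell median of -4.00 points (50 of 76 negative; -2.62 with balanced cells), with Rps19 at -24.1 and Rps23 at 21.9 points. Pluripotency genes had a median of -3.15 points (-1.88 with balanced cells), with Klf2 at -20.4 and Sox15 at -17.5 points. Zinc finger genes had a median of -2.53 points (-0.729 with balanced cells), with Zfp51 at 25.6 and Zfp54 at 23.6 points. Replication factor genes had a median of -2.15 points (-3.49 with cells between 20 and 80% replicated), with Gins2 at -21.4 and Pold1 at -19.7 points. Trophectoderm genes had a median of -1.13 points (-5.08 with cells between 20 and 80% replicated), with Krt18 at -19.7 and Tfap2c at -17.2 points. Olfactory receptor genes had a median of -0.634 points, which was 2.58 points with balanced cells, and Olfr33 and Olfr373 had shifts of 24.5 and -24.0 points.

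Against matched lists and rotations the 4-cell medians of long neuronal genes stood at percentiles 100 and 99, histone genes at 100 and 85.5, protocadherin genes at 100 and 83.3 and MHC genes at 0.02 and 6.17. Ribosomal protein genes stood at 16.9 and 1.42, zinc finger genes at 25.1 and 4.03, Hox genes at 14.3 and 19.4 and pluripotency genes at 34.3 and 19. Replication factor genes stood at 63.1 and 28, trophectoderm genes at 66.3 and 12.1 and olfactory receptor genes at 100 and 74.5.

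The bin at the midpoint of Rif1 itself, on chromosome 2, had shifts of 11.6, -4.49 and -6.45 points at the 4-cell, 8-cell and morula stages. It was replicated in 27 of 49 siCont and 36 of 51 siRif1 cells at the first of these. A DNA measurement says nothing of the level of Rif1 RNA or protein, so the knockdown could not be checked here.

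Early and late regions of control cells lay furthest apart at the morula stage, and the spread over bins differed less between stages in siRif1 cells. The SD over bins in siCont was 13.7, 19.8 and 25.8 points at the 4-cell, 8-cell and morula stages, and in siRif1 14, 14.7 and 17.3 points. Bins replicated in 40 to 60% of cells made up 49.6, 32.4 and 20.2% in siCont and 49.5, 46.4 and 39.1% in siRif1. Control 8-cell and morula profiles correlated at r = 0.908, and those of siRif1 at 0.699. Counting error was not removed and lowers such correlations more where the spread is small, as in siRif1 cells at these stages. The correlation of 4-cell with 8-cell profiles was 0.800 in siCont and 0.773 in siRif1, and that of 4-cell with morula profiles 0.730 and 0.721. Set against the control morula profile, siRif1 8-cell cells stood at r = 0.692, as did siRif1 4-cell cells, whereas control 8-cell cells stood at 0.908.

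Shifts at the 8-cell and morula stages correlated across bins at r = 0.497, positive on 19 autosomes. Those of the 4-cell stage correlated with the 8-cell shifts at r = 0.163 and with the morula shifts at r = 0.0468. Of bins at least 30 points later, 4 were shared by the 8-cell and morula stages, against 2.24 for independent sets. Of bins at least 30 points earlier, 3 were shared, against 0.627. These expectations treat bins as independent, although states run over at least 5 bins. A single overlap of shifted stretches could give such counts, so they do not show an excess.

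Pairs of cells at the same point of S phase correlated less in siRif1 than in siCont at the 8-cell and morula stages. At the 4-cell stage the order depended on the pair rule: the mean of 3 S phase strata was 0.0813 in siCont and 0.0556 in siRif1. The median correlation of matched pairs was 0.0553, 0.139 and 0.265 in siCont at the 4-cell, 8-cell and morula stages, over 108, 265 and 181 pairs. In siRif1 it was 0.0611, 0.0657 and 0.121, over 185, 223 and 161 pairs. A flatter profile over bins lowers such correlations by itself. Simulated cells drawn from the control shares had pair correlations of 0.0743, 0.155 and 0.265 at the 4-cell, 8-cell and morula stages. The lower siRif1 values at the 8-cell and morula stages are therefore not evidence separate from the smaller SD over bins. Whether cells differed beyond what their group profile gives was not tested. Quartile ranges of the pair values overlapped at every stage, from 0.0426 to 0.260 in siCont and from 0.0150 to 0.143 in siRif1 at the 8-cell stage and from 0.159 to 0.387 and 0.0540 to 0.194 at the morula stage. State switches per 100 Mb had medians of 43.8, 42.7 and 40.5 in siCont and 46.5, 46.6 and 41.5 in siRif1. SDs over cells were 5.31 to 11.2, which describe single cells and do not judge a difference between medians.

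**Figure D5:**
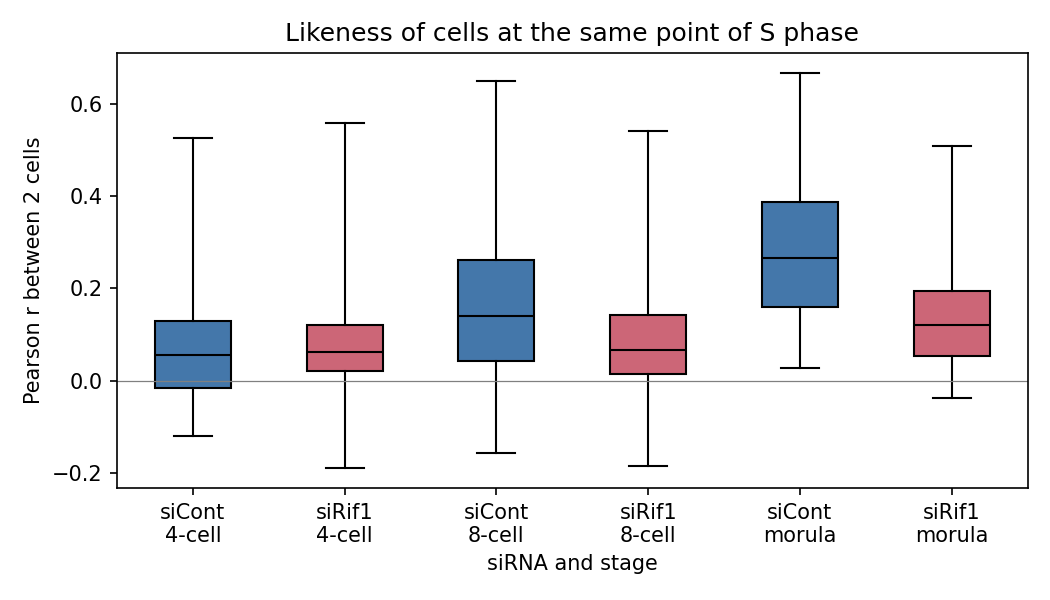
Pearson r between the states of cell pairs matched in percent replicated (y axis), by siRNA and stage; boxes span quartiles, lines mark medians and whiskers the range. Medians are 0.0553, 0.139 and 0.265 in siCont and 0.0611, 0.0657 and 0.121 in siRif1. A smaller SD of the replicated share over bins lowers these values by itself.

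By position along the autosomes, the distal of 5 equal parts had shifts of -1.22, -4.12 and -2.27 points at the 4-cell, 8-cell and morula stages, with SDs over autosomes of 4.2, 7.80 and 4.47, and was negative on 12, 10 and 12 autosomes. The centromere-proximal part had shifts of 1.47, 1.83 and 0.559 points, with SDs of 4.11, 7.13 and 4.77, and was positive on 13, 10 and 10 autosomes.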

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

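No paired analysis was possible because the numbers in the labels only name cells, and no result comes from a test. With no replicates, a value was taken as kept when it moved by less than the SD over autosomes, over cells for switches and over members for gene lists, or by less than 0.5 of the quartile range of pair values. Shares of bins were taken as kept within 1.5 times. These spreads were chosen after seeing the data and are wide, above all for lists. Of 36 values of bin shares 27 moved, and of 90 other values 10 moved. For 117 list values the SD over single members was too wide for a median to pass, so they are not counted as kept. Of these 6 changed sign, and the moves had a median of 0.700 and a maximum of 7.85 points. Another 15 values came from settings that changed nothing: no used bin was measured in under 90% of the cells of a group, and no run of 1 bin existed. They say nothing about stability. Alternatives with the X chromosome were not run. Depth per cell is unknown and its effect could not be examined.

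Correlations between treatments were 0.749 (4-cell) and 0.868 (morula) with cells thinned to matched S phase positions, which leaves fewer cells, and 0.720 (8-cell) with balanced cells. The late-minus-early difference was 15 (8-cell) and 1.75 points (morula) on percentile ranks, and 14.2 points (8-cell) with classes from the same stage. The SD over bins of 4-cell siCont was 15.1 points with cells between 20 and 80% replicated and 14.8 thinned, and that of morula siRif1 18.8 thinned. The correlation of 8-cell with morula shifts was 0.410 with balanced cells. The cause was not tested.

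The share of bins past the size rule depended most on settings. Earlier and later shares at 20 points were 1.36 and 1.24% (4-cell), 3.95 and 6.43% (8-cell) and 6.41 and 5.60% (morula). At 40 points they were 0 and 0.00217%, 0.00217 and 0.09997%, and 0.0109 and 0.0261%. With cells between 20 and 80% replicated they were 0.0934 and 0.128% (4-cell), 0.413% earlier (8-cell) and 0.776% later (morula). Balanced cells gave 0.0608 and 0.115% (4-cell) and 4.13% later (8-cell). Thinning gave 0.231 and 0.123% (4-cell), 0.535 and 2.27% (8-cell) and 0.974% later (morula). The running mean gave 0.0109 and 0.0283% (4-cell) and 0.369% earlier (morula). Stricter rules and fewer cells move such shares by construction; otherwise the cause was not tested.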

Other observations

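Shifts were ordered by gene density at the 8-cell and morula stages. At the 8-cell stage the gene-densest of 5 equal classes of bins (24.2 protein-coding genes per Mb) had a mean shift of -11.0 points, negative on 19 autosomes, and the poorest class (0.429 genes per Mb) one of 9.77 points. At the morula stage these were -8.16 and 13 points. At the 4-cell stage the 5 classes from poorest to densest had shifts of 0.410, 1.28, 1.58, 0.364 and -3.64 points, the last negative on 18 autosomes. The rank correlation of replicated share with gene density was 0.488, 0.652 and 0.709 in siCont at the 4-cell, 8-cell and morula stages and 0.390, 0.397 and 0.621 in siRif1. Of the tests given here, that of state switches was chosen after its values had been seen, as was the allowance for spread in the test of a subset of cells. The allowances for spread in the tests of S phase mix and of shared shifts were likewise not in the rules set beforehand.

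Early and late regions lay closer together in siRif1 cells at the 8-cell and morula stages. By percentile ranks, the order of bins also differed between treatments at the 8-cell stage, more than at the morula stage. With both groups thinned to the same S phase positions, 85.8% of the morula difference and 106% of the 8-cell difference remained. The SD over draws was 11.1% for the morula value. Both values passed the limit set beforehand for a shift beyond the mix of cells. The morula value does not pass it once this SD is taken off. A different mix of cells may therefore account for part of the morula value. A subset of uninformative siRif1 cells would leave the best cells like controls. The 90th percentile over cells of the correlation with control profiles of other stages stood -0.0697 (8-cell) and -0.123 (morula) from that of controls. With an SD over autosomes of up to 0.0448 the first of these leaves the question open, and such a subset would itself lower this percentile somewhat. The 10th percentile was lower too, at -0.114 in siRif1 and 0.0531 in siCont (8-cell) and 0.105 and 0.266 (morula). Errors in single bins cannot be judged, since no run under 5 bins is present in the tables and the excess of 3.90 and 1.09 switches per 100 Mb says nothing about them. Depletion of Rif1 is the difference the design names and remains one open explanation, as does noise that differed between groups before the states were called.

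Gene-dense regions were later in siRif1 cells at the 8-cell stage. A loss of early-late contrast alone does not account for it: within the earliest class of bins, the gene-densest had a shift -14.4 points from that of the gene-poorest, with the same sign on 19 autosomes. The same difference was -9.23 points at the 4-cell stage, also negative on 19 autosomes, so the pattern was not particular to the 8-cell stage. At the morula stage it was -2.21 points and negative on 10 autosomes. Uneven amplification of GC-rich DNA could give such a pattern in cells at every S phase position, and the gene-densest of 10 classes stood -5.68 and -7.40 points from the next class in siRif1 cells below and above their median percent replicated, against -1.47 and -5.45 points in siCont. GC content was not analysed here and an effect of Rif1 would give the same values, so amplification and Rif1 both stay open.

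Shifts at the 8-cell and morula stages correlated at 0.497 across bins. After the mean shift of each replication timing stratum was removed, the correlation was 0.108 (SD over autosomes 0.111), positive on 17 autosomes. Loss of contrast at both stages may therefore account for most of the correlation, and whether regions share a further shift is not settled by these values.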
